A study of Mus musculus with 6 samples.

How the data were processed

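Chromatin of RAW 264.7 cells treated with LPS at 100 ng/ml for 0, 4 or 10 h was precipitated with an antibody against hnRNP UL1 and sequenced beside input DNA, per the labels' protocols. The 6 samples were grouped by their titles into ChIP and input at each time, with 1 library per group. Peak tables of the 3 ChIP samples were used, and the input samples were not analysed here. Per the submitters' processing notes, CASAVA 1.8, BWA 0.7.12 and MACS2 2.1.0 were used with the mouse build GRCm38 (mm10). The notes give no roles, settings, thresholds or use of the input. Each table belongs to 1 sample. Per the file headers the authors deposited, for each peak, a chromosome, start, end and width, a genomic annotation, the nearest gene with its span, strand and Ensembl IDs, the distance to its start, its name and its description. Every peak is given as a point 2 bp wide. Whether this is the summit or the middle of the peak, and which tool made the annotation, is not given in the sources used here. Heights, fold enrichments, q-values, peak extents and read depths are not among the columns, so depth is unknown and no peak could be weighted.

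The tables are ordered by gene ID. The 4 h table broke off inside its last row, which was left out, and the 10 h table stopped at a lower ID than the others. Peaks were therefore compared between times only for nearest genes with IDs below ENSMUSG00000022416 (all times) or below ENSMUSG00000027620 (0 h and 4 h). Both end genes were left out, since their rows may be incomplete. These ranges named 2104 and 3435 genes, of which 2068 and 3369 were matched by symbol and chromosome to protein-coding genes of the RefSeq annotation of GRCm38.p6, the build of the tables. Of the gene names listed, 98.0% (0 h), 98.6% (4 h) and 98.2% (10 h) were found in that annotation. Gene spans come from it and strands from the tables. The reference annotation used here gives no Ensembl IDs, so genes without a row were not placed in a range. Members of a gene list without any row are therefore left out of its counts in the ranges.

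A peak was counted at a gene when its point lay in the gene or up to 5 kb upstream. Within a range of IDs, peaks whose nearest gene has an ID outside it were not counted, even inside a gene of the range. For the whole 0 h table, where the strand of genes without a peak is unknown, 5 kb to both sides was used. The promoter class is the authors' annotation of a start within 1 kb, for all genes. A peak was called shared when a point of the other list lay within 500 bp. Chance sharing was taken from 1000 placements in which each peak was moved to a random gene of the range at its own distance from the start. Other placements were made 200 times each. The share at starts was also compared with random genome positions whose nearest gene is in the range. The 13 gene lists were fixed before the data were examined: early and late LPS-induced, interferon-response, TLR4 and NF-kB signalling, macrophage identity, DNA damage response, hnRNP and splicing factor, replication-dependent histone, ribosomal protein, housekeeping, T and B cell, neuronal and hepatocyte genes. The peaks of a list were compared with 10000 random lists of genes of the range, which are genes named by at least 1 row, matched in 20 bins of gene length. For the whole 0 h table they were drawn from all 21883 protein-coding genes of the reference. This was done for lists with at least 5 members in the range. Ratios of shares have exact 95% intervals conditional on the sum of both counts, and shares have exact Clopper-Pearson intervals. Both cover counting error only.

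Several planned steps were changed once the columns were known. Overlap by base pairs became the distance between points, and placement along whole chromosomes became placement at other genes, because the tables of 4 h and 10 h hold part of the genome's genes. The promoter share covers all genes rather than protein-coding genes, which became an alternative. Motif counts and base content need a genome sequence and were left out. The rule for named genes had ranked peaks by q-value and fold. In its place genes were ranked by their number of peaks: the 10 with the most peaks at each time, the 10 with the most peaks over 500 bp from any peak of another time, and up to 4 members of each list. The 16 genes Tnf, Il1b, Il6, Nos2, Ptgs2, Nfkbia, Tnfaip3, Ccl2, Ccl5, Cxcl2, Cxcl10, Ifnb1, Hnrnpul1, Spi1, Actb and Alb were fixed beforehand. Genes of the whole 0 h table were named after their values were seen.

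The counting steps were tested on simulated data with the 4 h list and its 2068 genes. Planted sharing of 30.0% was recovered as 30.0%. This had to follow, as planted points lay within 500 bp of a 4 h peak and all others far away, so it checks the counting only. Of 100 random lists of 13 genes 8% lay above the 95th percentile, and of lists with 3 times the peaks 88% did. Settings planned before the data were examined and run were a distance of 200 bp, a shift of the whole list along each chromosome, promoters of 3 kb, merging of peaks under 500 bp apart, main chromosomes, and gene regions of 1000 bp around a start or 20 kb to both sides. Added after seeing the data were the longer ID range, all complete rows, a distance of 1000 bp, random thinning, 2 other placements, protein-coding rows, rows that name the gene, and lists without the member with the most peaks, also in the longer range. Computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.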

Results

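Binding of hnRNP UL1 to chromatin was mapped in RAW 264.7 cells, a mouse macrophage cell line, before and during stimulation with lipopolysaccharide (LPS), the bacterial cell-wall component that activates Toll-like receptor 4. hnRNP UL1 (heterogeneous nuclear ribonucleoprotein U-like 1) is a nuclear protein that binds RNA and takes part in RNA processing and in the response to DNA damage. Cells received LPS at 100 ng/ml for 0, 4 or 10 h, and chromatin was precipitated with an antibody against hnRNP UL1 and sequenced (ChIP-seq). The series holds 3 ChIP samples and 3 input samples, 1 of each per time. The data analysed here are the authors' peak tables of the 3 ChIP samples. Each complete row places 1 peak as a point and names its nearest gene. The tables carry no height, fold enrichment, q-value or extent of a peak, and no read depth, so a peak counts as present or not present. With 1 library per time there was no test between times and no p-value. Shares are given with exact 95% Clopper-Pearson intervals, which cover counting error only. Neighbouring peaks cluster and are not independent, so these intervals are too narrow for a difference between cultures.

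The table of 0 h held 8425 peaks, that of 4 h held 9046 complete rows and that of 10 h held 1153. These totals do not compare the times, because the tables are ordered by the Ensembl gene ID of the nearest gene and reach different IDs. The 4 h table ended within a row of ENSMUSG00000027620, and the 10 h table ended at ENSMUSG00000022416, whereas the 0 h table ran to ENSMUSG00000117337. Comparisons of all times therefore used peaks whose nearest gene has an ID below the end of the 10 h table, and some comparisons of 0 h with 4 h used the longer range up to the end of the 4 h table. What follows describes those genes, not the genome. Peaks inside such a gene are missed where the nearest gene named for them has an ID outside the range.

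**Figure D1:**
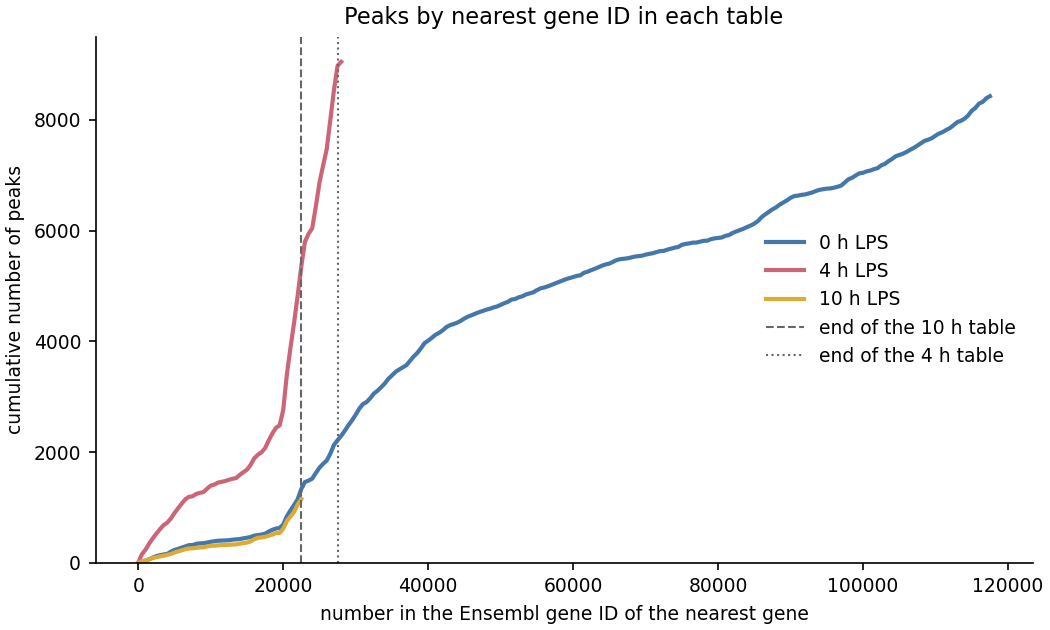
Cumulative number of peaks (y axis) against the number in the Ensembl gene ID of the nearest gene (x axis) in each table, with dashed and dotted lines at the ends of the 10 h and 4 h tables. Up to the dashed line there are 5298 peaks at 4 h, 1312 at 0 h and 1152 at 10 h.

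The first comparison asked where hnRNP UL1 peaks lay after 4 h of LPS and before it. Over the common gene IDs there were 1312 peaks at 0 h and 5298 at 4 h, a ratio of 4.04, and this ratio lay between 3.68 and 4.50 in 5 parts of the ID range. The 4 h peaks were spread over 1835 nearest genes with 2.89 peaks each, and the 0 h peaks over 791 genes with 1.66 each. Of 2068 protein-coding genes, 855 had peaks in the gene or the 5 kb upstream of it at 4 h alone, 152 at 0 h alone and 216 at all 3 times. At 4 h 54 genes held at least 10 peaks, against 4 genes at 0 h. In the longer ID range the numbers were 2225 at 0 h and 9045 at 4 h, a ratio of 4.07.

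The genes with the most peaks at 4 h carried long series of peaks along their bodies. Tmcc3 (ENSMUSG00000020023, chromosome 10, 94311682 to 94590954), which encodes a transmembrane coiled-coil protein, held 44 peaks at 4 h, 2 at 0 h and 8 at 10 h. Cd274 (ENSMUSG00000016496, chromosome 19, 29362107 to 29388095), the gene of the immune checkpoint ligand PD-L1, held 25 peaks at 4 h and 16 at 10 h, with 0 at 0 h. St3gal1, a sialyltransferase gene, held 33 at 4 h against 1 at 0 h and 9 at 10 h. Cpeb4, which encodes an RNA-binding protein acting on polyadenylation, held 37 at 4 h, 8 at 0 h and 21 at 10 h. Tns3 and Mbnl2, a splicing regulator gene, held 25 peaks each at 4 h, against 9 and 8 at 0 h. The others of the 10 genes with the most 4 h peaks were Pik3r5 (24 peaks), Abr and Asap1 (23 each) and B4galt5 (21), with 6, 2, 6 and 6 peaks at 0 h. In the longer ID range Slco3a1, a transporter gene on chromosome 7, came first with 65 peaks at 4 h and 0 at 0 h. There Cflar, whose product restrains caspase-8, held 38 peaks against 1, and Rbms1 held 27 against 3. Other genes of that range held many peaks at both times: Zeb2, a transcription factor gene, had 33 at 0 h and 44 at 4 h, and Rgl1 had 27 and 38.

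**Figure D2:**
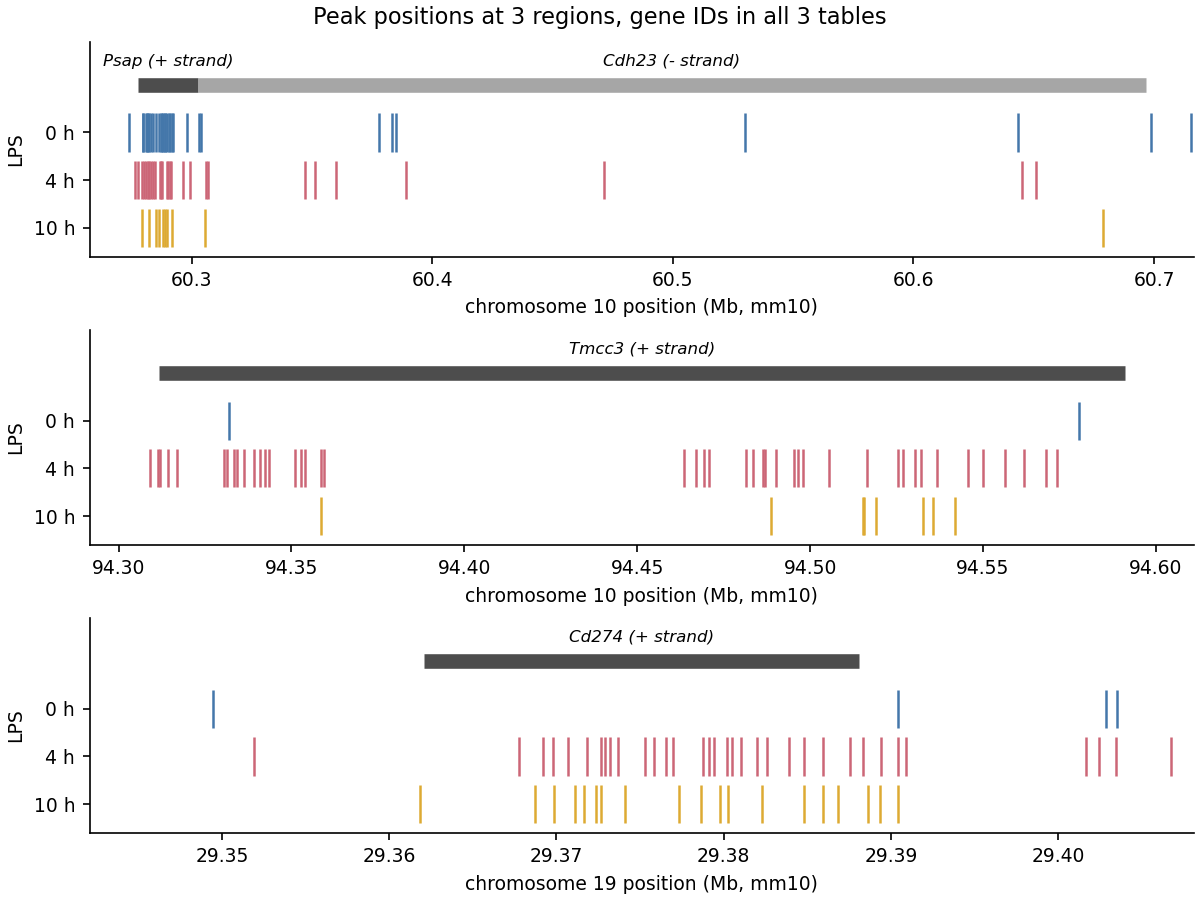
Positions of peaks (vertical lines, x axis in Mb of mm10) at 0, 4 and 10 h of LPS around Psap and Cdh23 on chromosome 10, Tmcc3 on chromosome 10 and Cd274 on chromosome 19, with the genes as bars above. The Tmcc3 region holds 2, 44 and 8 peaks at 0, 4 and 10 h, the Cd274 region 4, 34 and 19, and the Psap region 31, 28 and 10.

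Genes known to be induced by LPS held peaks at 4 h. Here and below, the members of a list in a range are only those that a row of some table names, so members without any peak are left out of counts and percentiles. The preset list of early LPS-induced genes, 38 genes in all, had 13 such members in the common range, with 42 peaks at 4 h, 4 at 0 h and 12 at 10 h. Cd40, a costimulatory receptor gene, held 11 peaks at 4 h and 0 at 0 h. Tnfaip3, which encodes the NF-kB inhibitor A20, held 7 and 0, Cd83 held 5 and 0, and Rel, an NF-kB subunit gene, held 5 and 1. By rows naming the gene as nearest, Cd40, Tnfaip3, Cd83 and Rel had 15, 14, 16 and 4 at 4 h. At 0 h these genes had 0, 1, 2 and 1, so an absence at 0 h can depend on the counted region. More 4 h peaks fell in this list than in 99.99% of 10000 random lists matched on gene length, which held 15.4 on average. The number of members with a 4 h peak, 11 of 13, stood lower, at the 88.8th percentile, and at the 71.2nd in the longer range, among lists drawn from genes named in the same way. By number of peaks at 0 h the list stood at the 46.9th percentile, and at the 95.7th in the longer range, where it held 12 peaks against 6.59 in random lists. As a share of all peaks the list held 7.93 per 1000 peaks at 4 h (95% interval 5.72 to 10.7) and 3.05 per 1000 at 0 h (0.831 to 7.79). The ratio of the shares was 2.60 with an interval from 0.943 to 9.98, which includes 1, and it was 0.743 when peaks within 1000 bp of a start alone were counted. In the longer ID range the list had 21 members and the ratio was 1.35 (0.725 to 2.75). Among length-matched random lists the 2 ratios stood at the 95.2nd and 77.7th percentiles. In that range Atf3 held 4 peaks before and 9 after LPS, and Nfkb2 held 3 and 3.

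Among late LPS-induced genes the list had 9 members in the common range, with 26 peaks at 4 h, 3 at 0 h and 6 at 10 h. Acod1, which makes the metabolite itaconate, held 8 peaks at 4 h and 0 at 0 h, and Nos2, the inducible nitric oxide synthase gene (ENSMUSG00000020826, chromosome 11, 78920787 to 78960226), held 7 and 0. Mmp14 held 4 and 1, and the cytokine gene Il10 held 3 and 1. Of the random lists 99.7% held fewer 4 h peaks. The number of members with a 4 h peak, 8 of 9, stood at the 89.3rd percentile, and at the 55.2nd in the longer range. The share ratio of 4 h over 0 h was 2.15 (0.658 to 11.1), an interval that includes 1, and it was 0.248 for peaks within 1000 bp of a start. It stood at the 84.5th percentile of random lists, and at the 87.5th in the longer range.

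Interferon-response genes held their peaks at few loci. The adjacent genes Cmpk2 and Rsad2 (chromosome 12), both interferon-inducible and the latter encoding the antiviral protein viperin, held 13 and 11 peaks at 4 h, 0 each at 0 h, and 0 and 1 at 10 h. Irf1 and Irf9 held 1 peak each at 0 h and at 4 h. In all 4 members of the common range there were 26 peaks at 4 h, 2 at 0 h and 1 at 10 h, a share ratio of 3.22 for 4 h over 0 h (0.806 to 28.0). In the longer range 7 members held 56 peaks at 4 h and 4 at 0 h, a ratio of 3.44 whose interval (1.27 to 13.1) lies above 1. Without its top member Ifih1 it was 3.12, with an interval from 0.989 to 15.8 that includes 1. Among length-matched random lists the ratio of 3.44 stood at the 91.5th percentile. In the common range the ratio without the top member was 1.61. The RNA sensor gene Ifih1, which lies in the longer range alone, held 18 peaks at 4 h against 1 at 0 h. For peaks within 1000 bp of a start in the common range the ratio was 0.495.

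For genes that pass on the LPS signal, the 8 members of the TLR4 and NF-kB signalling list held 22 peaks at 4 h, 5 at 0 h and 9 at 10 h, with a share ratio of 1.09 (0.403 to 3.68) for 4 h over 0 h and the 73.8th percentile among random lists at 4 h. At 10 h 6 of the 8 members had a peak, against 2.49 in random lists (99.4th percentile), and the number of peaks stood at the 93.7th. The difference from the LPS-induced lists was not tested, and the intervals of the ratios overlap. Tnip1 held 6 peaks at 4 h, Tbk1 and Tab2 held 5 each, and Mapk8 held 2.

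Macrophage identity genes held peaks at every time. Their 7 members in the common range had 22 peaks at 0 h, 41 at 4 h and 24 at 10 h, above 99.9%, 99.8% and 99.8% of the random lists. By members with a peak the list stood at the 97.4th, 91.3rd and 78.4th percentiles, with 3 of 7 members at 10 h. The cathepsin B gene Ctsb (ENSMUSG00000021939, chromosome 14, 63122462 to 63145923) alone held 16, 17 and 19, which leaves 6, 24 and 5 for the others. Spi1, the gene of the myeloid transcription factor PU.1, held 2, 9 and 3, Fcgr1 held 1, 5 and 2, and Mertk held 0, 6 and 0. The share of peaks at this list was lower at 4 h than at 0 h, with a ratio of 0.462 (0.269 to 0.814), the 11.8th percentile of random lists, but without Ctsb the ratio was 0.991. In the longer range 13 members held 36 peaks at 0 h and 67 at 4 h, a ratio of 0.458 (0.301 to 0.707) at the 4.91st percentile. Without Ctsb it was 0.615 there, with an interval from 0.360 to 1.09 that includes 1.

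**Figure D3:**
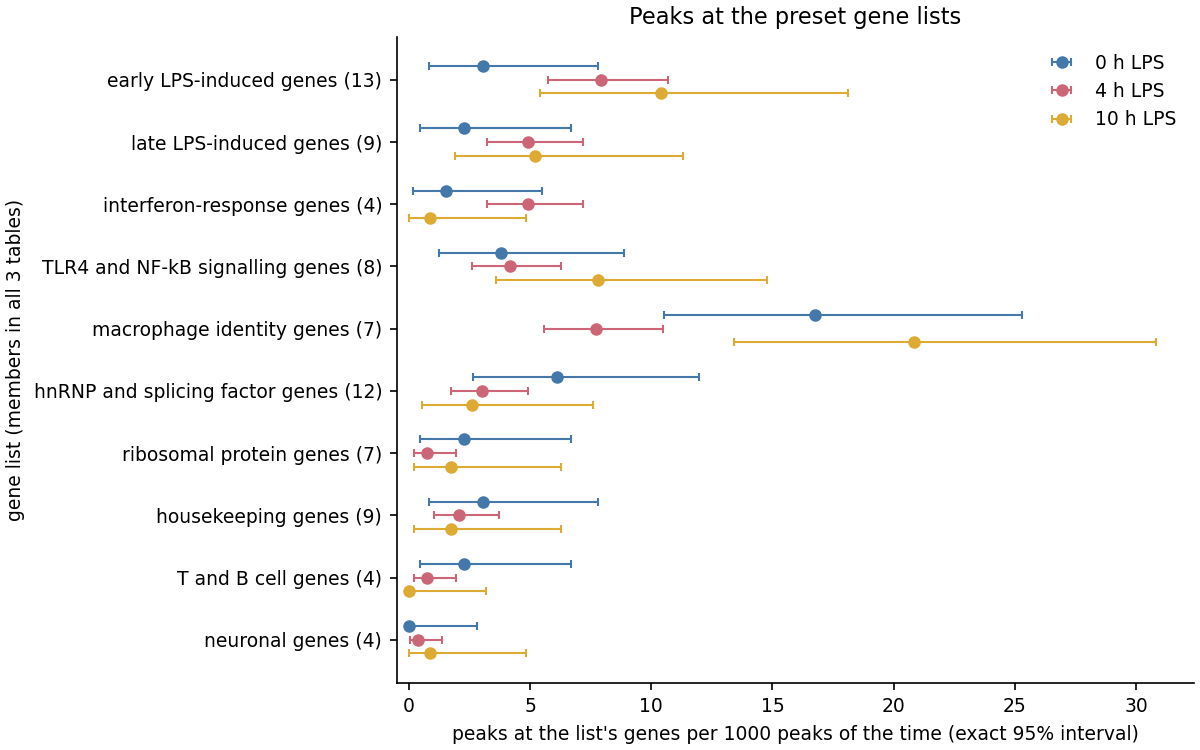
Peaks at the genes of each preset list per 1000 peaks of the time (x axis), with exact 95% intervals, at 0, 4 and 10 h of LPS; the number of members in the common gene IDs stands in parentheses. Early LPS-induced genes lie at 3.05, 7.93 and 10.4 per 1000 peaks and macrophage identity genes at 16.8, 7.74 and 20.8.

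The remaining lists held few peaks in the common range. The 12 hnRNP and splicing factor genes had 8 peaks at 0 h, 16 at 4 h and 3 at 10 h, with Taf15 at 5 and Hnrnpd and Ewsr1 at 2 each at 4 h. Their share ratio of 4 h over 0 h was 0.495 (0.200 to 1.34), and 0.430 (0.202 to 0.960) in the longer range. The 9 housekeeping genes had 4, 11 and 2 peaks, of which Ywhaz held 6 at 4 h, and the 7 ribosomal protein genes had 3, 4 and 2. The 3 DNA damage response genes had 2, 5 and 1, with Brca1 at 3 and Rad50 at 2 at 4 h. Of the cell types the culture should lack, the 4 T and B cell genes had 3, 4 and 0 peaks, the 4 neuronal genes 0, 2 and 1 and the 2 hepatocyte genes 0, 1 and 1. No replication-dependent histone gene was named in the common range.

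Of the 16 single genes fixed beforehand, Nfkbia, the gene of the NF-kB inhibitor IκBα, held 5 peaks at 4 h, with 0 at 0 h and 0 at 10 h. Peaks naming Nfkbia as nearest gene at any distance numbered 8 at 4 h, 1 at 0 h and 1 at 10 h. Nos2, Tnfaip3 and Spi1 are given above, and Il6 held 0 peaks at 0 h and 0 at 4 h. At 4 h 1 peak outside its counted region named Il6 as nearest gene. In the 0 h table, Tnf, Il1b, Ptgs2, Ccl5, Cxcl2, Cxcl10, Ifnb1, Alb and Hnrnpul1 itself had 0 peaks within 5 kb of the gene, and Ccl2 and Actb had 1 each. The ID of Actb (ENSMUSG00000029580) lies beyond the ends of the 4 h and 10 h tables. For the other 10 genes, which no row names, it was not determined here whether those tables reach their IDs.

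The comparison of 10 h with 4 h and 0 h asked what followed after longer exposure. Over the common IDs there were 1152 peaks at 10 h, 0.217 times the number at 4 h and 0.878 times the number at 0 h. Of the genes with a 10 h peak 80.3% (76.8 to 83.5%) also held a 4 h peak, and 42.9% (38.8 to 47.1%) held a 0 h peak. Of the genes with a 0 h peak 73.8% (70.3 to 77.1%) held a 4 h peak. Of all 2068 genes 77.5% held a 4 h peak and 33.2% a 0 h peak. These are not fair base rates, because the 2068 genes are themselves those that a peak of some time names, mostly of 4 h. Besides Cpeb4, Ctsb and Cd274, the genes with the most 10 h peaks were Arid5b, a chromatin regulator gene, with 13 and Aoah with 11. Aoah encodes acyloxyacyl hydrolase, the enzyme that inactivates LPS, and held 16 peaks at 4 h and 0 at 0 h. Lrp12 and St3gal1 held 9 each, and Psap, Tmcc3 and the corepressor gene Ncor1 held 8 each. Ncor1 had 7 peaks at 4 h, and all 8 of its 10 h peaks lay over 500 bp from any of these. The early LPS-induced list held 12 peaks at 10 h, above 98.9% of the random lists, and its share was 3.42 times that at 0 h (1.04 to 14.5). This depended on the counting, with 1.99 (0.780 to 5.48) by rows naming the gene and 1.71 (0.196 to 20.5) within 1000 bp of a start.

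Over the common gene IDs the most peaks before LPS were found at Psap, which encodes the lysosomal protein prosaposin (ENSMUSG00000004207, chromosome 10, 60277628 to 60302600). It held 22 peaks at 0 h, 19 at 4 h and 8 at 10 h. Ctsb came next with 16, then Lrp12 with 13 and Zmiz1, a transcriptional coregulator gene, with 12. The order depends on the counting here too, since only 6 rows name Lrp12 at 0 h, against 14 for Tns3, 13 for Mtss1 and 12 for Zmiz1. All 12 Zmiz1 peaks and 12 of the 13 Lrp12 peaks counted at 0 h lay over 500 bp from any 4 h peak of the common IDs. In all, Zmiz1 held 15 peaks of the common IDs at 4 h and Lrp12 held 10. The whole 0 h table, counted with 5 kb to both sides, holds 22 peaks at Zmiz1 and 14 at Lrp12, so not every peak is covered. Slc29a3, a nucleoside transporter gene, held 7 peaks at 0 h, 2 at 4 h and 0 at 10 h. Dnmt3a, a DNA methyltransferase gene, held 7, 14 and 1.

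Positions were compared next. Of the 0 h peaks 19.1% (17.0 to 21.4%) lay within 500 bp of a 4 h peak. When each 0 h peak was moved to another gene at the same distance from its start, 8.71% did so on average, with a range of 6.33 to 11.9% over 1000 placements. Of the 10 h peaks 20.3% (18.0 to 22.8%) lay within 500 bp of a 4 h peak, against 6.62% (range 4.60 to 9.03%) for moved peaks. The share of 10 h peaks near a 0 h peak was 7.99% (6.49 to 9.70%), against 2.65%. These shares grow with the length of the other list, and the 4 h list is the longest. With lists thinned at random to the shortest, a choice made after the results were seen, 5.004% of the 10 h peaks and 4.48% of the 0 h peaks lay near a 4 h peak. Both lie below the share of 10 h peaks near a 0 h peak, but that share comes from unthinned lists, and thinning by itself lowers a share. No closer likeness of 10 h to 4 h can therefore be read from positions. Among 0 h peaks within 1 kb of a start 26.99% (22.95 to 31.3%) lay near a 4 h peak, and among intron peaks 14.1% (10.9 to 17.8%). Near a 10 h peak lay 7.52% of the 0 h promoter peaks and 7.53% of the 0 h intron peaks. Chance values were not computed per class. There were 42 peaks of the 10 h list near peaks of both other times. With peaks kept at their own gene and placed anew, chance sharing was 10.7% for 0 h with 4 h.

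**Figure D4:**
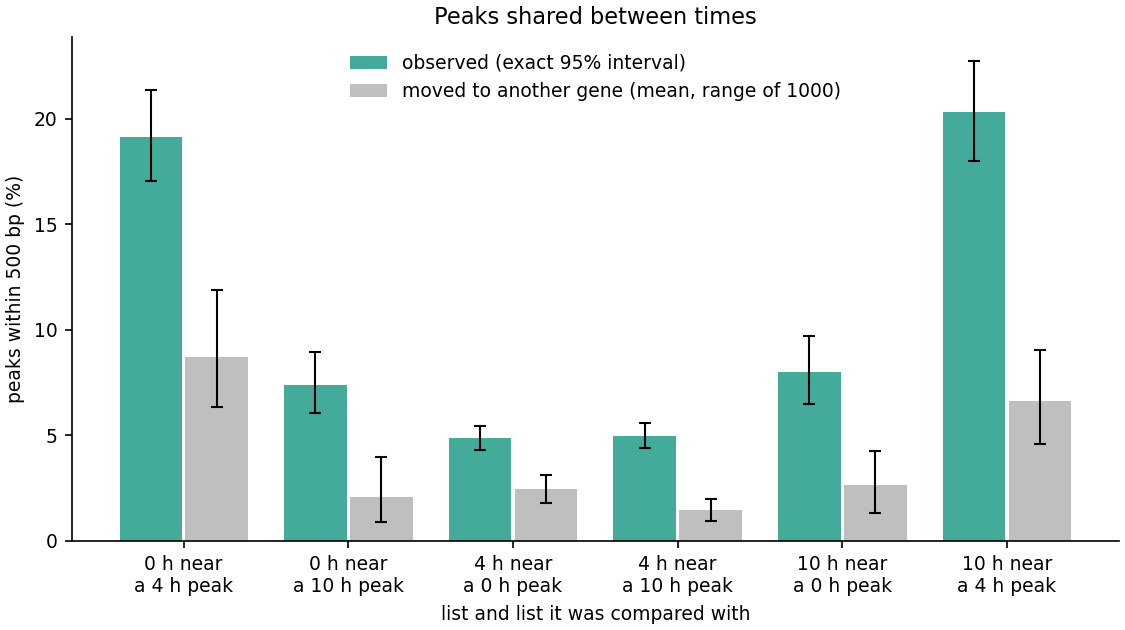
Share of the peaks of each list that lie within 500 bp of a peak of another list (y axis, percent), observed with its exact 95% interval and after moving each peak to another gene (mean and range of 1000 placements). Of the 0 h peaks 19.1% lie near a 4 h peak, against 8.71% of moved peaks, and of the 10 h peaks 20.3%, against 6.62%.

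Peaks at 0 h lay at promoters more often than peaks under LPS. By the authors' annotation 34.5% (31.9 to 37.1%) of the 0 h peaks lay within 1 kb of a transcription start, against 20.1% (18.99 to 21.2%) at 4 h and 20.8% (18.5 to 23.3%) at 10 h. Introns held 32.4% (29.86 to 35.001%) of the peaks at 0 h, 40.7% (39.4 to 42.0%) at 4 h and 42.2% at 10 h, and distal intergenic sequence held 14.5%, 16.9% and 15.5%. The 4 h list nevertheless held more promoter peaks in number, 1063 against 452 at 0 h and 240 at 10 h. At all times starts were far more frequent than at random positions. Within 1 kb of the reference's 5' ends lay 25.04% of the 0 h peaks, 12.5% at 4 h and 12.7% at 10 h, against 1.52% of random positions. Of the peaks within 1 kb of a start 37.4% (32.9 to 42.0%) lay upstream of it at 0 h, 45.0% (41.9 to 48.0%) at 4 h and 46.3% (39.8 to 52.8%) at 10 h. The median distance to a start was 3721 bp at 0 h, 5696 bp at 4 h and 5832.5 bp at 10 h.

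**Figure D5:**
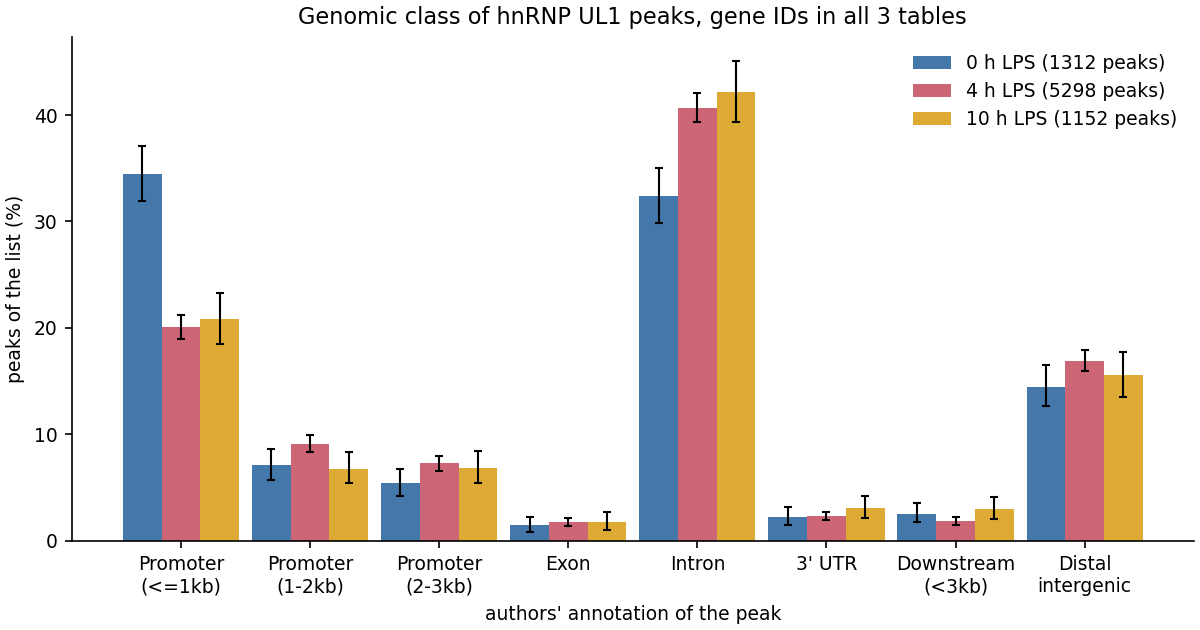
Share of peaks (y axis, percent, exact 95% intervals) in each class of the authors' annotation (x axis) at 0, 4 and 10 h of LPS, for gene IDs in all 3 tables. The class within 1 kb of a start holds 34.5%, 20.1% and 20.8%, and introns hold 32.4%, 40.7% and 42.2%.

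The 0 h table, which runs through all gene IDs, allowed a view of unstimulated cells across the genome. Of 21883 protein-coding genes 19.3% held a 0 h peak within the gene or 5 kb of it. Counted in this way Lrmda, which is 1036590 bp long, held 47 peaks, Rgl1 39, Zeb2 35, Fnip2 27 and Psap 24. The order depends on the counting, since 19 rows name Lrmda, 37 Zeb2, 32 Rgl1 and 25 Fnip2. Litaf, which encodes a lysosomal membrane protein induced by LPS, held 19, Atp6v0d2, a subunit gene of the proton pump of lysosomes, held 18, and Gpnmb held 16. Several preset lists held peaks more often than length-matched random lists. Of 40 hnRNP and splicing factor genes 23 had a peak, against 7.35 in random lists, and of 30 housekeeping genes 16, against 4.36. Of 61 ribosomal protein genes 17 had a peak (random mean 6.29), of 40 TLR4 and NF-kB signalling genes 20 (9.38), and of 31 macrophage identity genes 15 (6.22). Among early LPS-induced genes 12 of 38 already held a peak before LPS, against 5.34 in random lists, above 99.7% of these. Late LPS-induced genes (5 of 30, random mean 4.64), interferon-response genes (7 of 29, 4.73) and DNA damage response genes (9 of 34, 8.67) lay within the random range. The neuronal list had a peak at 1 of 30 genes, against 7.12, and the hepatocyte list at 3 of 30, against 5.10. For T and B cell genes the number was 5 of 30, against 6.18, and for replication-dependent histone genes 0 of 34, against 0.768.

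By chromosome, the 0 h table held 3.10 peaks per Mb, with chromosome 11 at 1.76 times and the X chromosome at 0.127 times this value, and 0 peaks on the Y chromosome. Between times, chromosomes were compared over the common gene IDs. The share of peaks on chromosome 5 was lower at 4 h than at 0 h, with a ratio of 0.489 (0.334 to 0.727), and that on chromosome 8 likewise, with 0.544 (0.380 to 0.788). On chromosome 15 it was 0.698 (0.571 to 0.858). Chromosome 2 had a ratio of 1.33 (1.02 to 1.76) and chromosome 12 of 1.32 (1.05 to 1.68). Out of all chromosomes with peaks, only those whose interval leaves out 1 are named here. Peaks cluster at single genes, so these intervals are too narrow.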

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

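The tests of explanations in this part were all chosen after the results were seen. The 0 h table held signal outside the comparisons of times: 6200 of its peaks lay at gene IDs beyond the end of the 4 h table. In addition, 2754 of its peaks (32.7%) had a nearest gene without a name in the table, and 11.9% (10.7 to 13.2%) of these lay within 1 kb of a start, against 34.97% of the peaks with a named gene. The unnamed gene with the most peaks was ENSMUSG00000115875, with 20 peaks between 67599488 and 67890131 on chromosome 15. The next were ENSMUSG00000114967 on chromosome 14 with 19, which lie inside the span of Lrmda, and ENSMUSG00000102069 on chromosome 15 with 17.

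There were 4.04 times as many peaks at 4 h as at 0 h over the same gene IDs. A difference in table coverage would leave a ratio near 1 inside the common IDs, and the lowest ratio over 5 parts was 3.68. More sensitive calling of the same point sites would find most 0 h points again, but 26.7% (24.3 to 29.2%) lay within 1000 bp of a 4 h point. Within 10 kb 62.8% (60.1 to 65.4%) had a 4 h peak, so deeper calling of the same broader regions stays open. The LPS treatment cannot be told apart from a difference between libraries or their depth, since there was 1 library per time.

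The promoter share was higher at 0 h than under LPS. If a shorter list kept mainly promoter sites, the 10 h list should share the high value, but it held 20.8% (18.5 to 23.3%). The 10 h list also differs from the 0 h list in LPS treatment and library, so this does not settle the point for 0 h. A different gene annotation behind the 0 h table was tested with the same 5' ends for all lists. The share was then 2.01 times (1.74 to 2.31) as high at 0 h as at 4 h, which argues against differing start positions alone. The test cannot exclude a different annotation, because each list had been chosen by the nearest-gene IDs of its own table. Over all rows the 0 h promoter share was 27.4%, against 34.5% in the common IDs. A different annotation, a library or calling difference of the 0 h sample and an effect of LPS all stay open, with 1 library per time.

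The third pattern is the number of 4 h peaks at the 26 early and late LPS-induced and interferon-response genes, 94 against 9 at 0 h and 19 at 10 h. The larger number of peaks at 4 h is argued against for the pooled genes, but not settled. The 4 h list thinned to the 0 h number held 23.3 peaks there (15 to 32 in 95% of draws). The share ratio was 2.61 (1.21 to 6.996 with genes resampled), at the 98.4th percentile of random lists. In the longer range it was 1.94 over 40 genes, at the 97.0th percentile, and no interval with genes resampled was computed. List by list the ratios stood at the 77.7th, 87.5th and 91.5th percentiles in that range. The pool was formed after the results were seen, and leaves out the TLR4 and NF-kB signalling list, with a ratio of 1.09. The pool of 26 genes is therefore no independent test. Gene length is argued against, as these genes held more 4 h peaks than 100% of the length-matched random lists, but they also stood at the 99.2nd percentile at 10 h, so that excess is not particular to 4 h. Open chromatin of any active gene stays open, since the input libraries were not analysed and other lists went both ways: housekeeping, ribosomal protein and hnRNP and splicing factor genes stood at the 54.2nd, 17.3rd and 67.3rd percentiles and macrophage identity genes at the 99.8th. Within 1000 bp of a start the share ratios of the 3 lists were 0.743, 0.248 and 0.495, on few peaks, and a link to LPS-induced transcription is a hypothesis not tested here.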

How the results depend on the processing

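No paired analysis was possible because each time has 1 library and the labels give no replicate numbers. Alternatives with the longer ID range, all rows, 1000 bp, thinning, own-gene or uniform placement, protein-coding rows, rows naming the gene, or without the top member were chosen after seeing the data. Settings fixed beforehand with a stricter q-value or fold, lists of the strongest peaks, overlap by 50% of both peaks, soft-masked bases, motifs and base content were not run, since they need columns or a genome sequence not used here, and the chromosome result has no alternative left. Depth is unknown, so peaks missed for lack of reads cannot be told from absent ones. Where no cause is given, the cause was not tested.

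Merging peaks or keeping main chromosomes left the numbers of peaks within 1.5 times of those reported. The longer ID range holds more genes, with 2225 peaks at 0 h and 9045 at 4 h. All complete rows gave 8425 and 9046, and ratios of 1.07 for 4 h over 0 h and 0.127 for 10 h over 4 h, because the tables end at different IDs.

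Shared shares moved with the distance by construction. At 200 bp they were 10.4% (0 h near 4 h), 3.81% (0 h near 10 h), 2.59% (4 h near 0 h), 2.45% (4 h near 10 h), 4.34% (10 h near 0 h) and 11.2% (10 h near 4 h). At 1000 bp they were 26.7%, 10.1%, 7.49%, 7.64%, 10.9% and 28.8% in the same order. Thinning to the shortest list gave 4.48% for 0 h near 4 h and 5.004% for 10 h near 4 h. With peaks kept at their gene the excess over chance was 1.78, 1.92 and 2.03 fold for 0 h near 4 h, 10 h near 4 h and 10 h near 0 h. In the same order it was 47.9, 46.8 and 80.3 fold with the list shifted. With uniform placement it was 43.7, 49.9 and 73.9 fold. Both of the latter placements spread peaks over whole chromosomes, but the lists hold peaks at part of the genes only. High folds were therefore built in and give no support.

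Promoters of 3 kb held 47.0%, 36.5% and 34.5% at 0, 4 and 10 h, by construction, and all rows at 0 h gave 27.4%.

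The share ratio of 4 h over 0 h turned below 1 within 1000 bp of a start for early (0.743) and late LPS-induced (0.248), interferon-response (0.495) and TLR4 and NF-kB genes (0.330), on few peaks. For the last list it was also 0.686 with 20 kb to both sides, 0.867 by rows naming the gene, 0.991 without its top member and 0.765 in the longer range. Intervals lay above 1 for early genes at 2.81 (20 kb) and 2.20 (rows naming the gene), for late genes at 3.41 and 3.47, and for interferon genes at 3.44 in the longer range. Without Ifih1 the interval of the interferon genes there included 1 (3.12, 0.989 to 15.8). Intervals came to lie below 1 for T and B cell (0.281) and hnRNP genes (0.430) in the longer range, housekeeping genes with 20 kb (0.460), and hnRNP genes within 1000 bp of a start (0.248). The ratio of 10 h over 0 h for early genes had intervals that include 1 within 1000 bp of a start (1.71), by rows naming the gene (1.99) and without its top member (3.13). For macrophage identity genes the interval came to include 1 within 1000 bp of a start (0.743) and without Ctsb (0.991, and 0.615 in the longer range). Of the numbers of peaks at the lists under alternatives, 67 stayed within 1.5 times and 73 did not.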

Other observations

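The tests in this part were all chosen after the results were seen. Lysosome genes were prominent among the 0 h peaks. Psap held 24 peaks in the whole 0 h table, Atp6v0d2 held 18, Ctsb 17 and Gpnmb 16. The hypothesis that 0 h peaks gather at lysosome genes beyond what gene length gives was tested on 43 lysosome genes whose peaks had not been looked at. Of these, 28 held a 0 h peak, against 8.91 in length-matched random lists, and 100% of 10000 such lists held fewer. This goes with the hypothesis, but housekeeping genes also held peaks more often than random lists, at 16 of 30 genes, so the result may not be particular to lysosome genes.

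A further hypothesis was that the share of peaks at lysosome genes is lower at 4 h than at 0 h. Over the common gene IDs 18 lysosome genes held 63 peaks at 0 h, 80 at 4 h and 32 at 10 h, a share ratio of 0.314 (0.223 to 0.445) for 4 h over 0 h. Most of these peaks lie at genes already seen. For the 13 members not seen beforehand the ratio was 0.660 (0.357 to 1.29), which leaves the question open. In the longer ID range the 20 members not seen beforehand gave 0.551 (0.338 to 0.922). Among length-matched random lists these ratios stood at the 25.02nd and 10.2nd percentiles, so neither is unusual.

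Peaks formed clusters at all times. At 4 h 64.0% of the peaks had a neighbour of the same list within 10 kb, against 36.1% at 0 h and 36.0% at 10 h. Thinned at random to 1152 peaks the 4 h list had 28.0% (24.7 to 31.3% in 95% of draws) and the 0 h list 33.4% (31.9 to 34.98%). The 10 h list, which needed no thinning, has an interval of 33.2 to 38.9%, so no order of 0 h and 10 h can be read. Among intron peaks 39.3% (34.6 to 44.1%) lay in the first intron at 0 h, 31.3% (29.4 to 33.3%) at 4 h and 30.5% (26.4 to 34.8%) at 10 h. The share of peaks on chromosome 6 was higher at 10 h than at 4 h, with a ratio of 1.54 (1.16 to 2.03), and that on chromosome 12 was lower, with 0.667 (0.510 to 0.860). For the X chromosome, with 29 peaks at 4 h and 0 at 10 h, no interval was computed. All other chromosomes with an interval had one that includes 1 and are not named.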
